A study of Mus musculus with 2 samples.

How the data were processed

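ATAC-seq peak lists of 2 biological replicates of mouse neural tube at embryonic day 13.5 were analysed, with both samples in 1 group. The labels call them separate biological replicates from pooled male and female embryos. The deposited lists give 1 line per summit on the build mm10, per the labels. For each replicate there was an IDR-ranked, an IDR-thresholded and a pseudoreplicated list, and for both replicates together there were ranked, IDR-thresholded, conservative IDR-thresholded, replicated and pseudoreplicated lists. IDR, the irreproducible discovery rate, is the expected share of irreproducible peaks among those that pass, judged from how alike peaks rank in separate parts of the data. The aligner, the peak caller, the read filters and any shift of reads for the transposase cut were not given in the sources used here.

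The authors deposited for each summit a signal value, which is a fold or ratio over background, a p-value and a q-value as −log10, a score and the summit position, and in the ranked lists the −log10 of the IDR. What these hold was checked on the values. In the pseudoreplicated lists, the ratio and the −log10 p-value deposited by the authors matched (reads + 1) / (background + 1) and a Poisson tail with 1 constant background in 30, 29 and 30 of the 30 commonest pairs of values (tolerance 0.02). The background was 4.59 reads in replicate 1, 3.48 in replicate 2 and 8.07 in the pooled list, where the replicates sum to 8.07. Depth is therefore known only relative to each other, and a weak region in replicate 2 rests on fewer reads. In the ranked list of each replicate, the score deposited by the authors was set by the IDR in 100% of summits. The thresholded lists held the summits of the ranked lists at an IDR of 0.05 or lower, except for 173 and 169 summits removed in replicates 1 and 2 and 230 in the conservative list.

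Intervals that overlapped within a list were merged into regions on the 21 chromosomes, each with the position and signal of its strongest summit. The conservative list of the series was the main list, called here the tissue list, and the thresholded list of each replicate gave the values per replicate. Signal is the authors' value, used to describe and rank regions within a list, to correlate the replicates and, in the closing part, to compare regions with and without a site and the 2 groups of Hox genes by permutation tests. A mean ± SD of signal at a promoter is over the replicates, where both had a region. Regions of the replicates were shared if they overlapped by at least 1 base, and chance was taken from 100 circular shifts of the positions within each chromosome.

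Gene positions came from the protein-coding genes of the GENCODE annotation of the same assembly, 21853 genes with 54327 start sites, and 0 regions ended past a chromosome end. Regions were classed by their strongest summit as promoter (within 1 kb of a start site), exon, intron or intergenic. A gene had a promoter region if a region overlapped 1 kb either side of any of its start sites. Other regions were distal and were assigned to the nearest start site up to 500 kb away. Only start sites of protein-coding transcripts were used, so other promoters more than 1 kb from these count as distal. The 20 gene lists, the 27 consensus sequences, the tests and the rule for the genes named were fixed before the data were examined. The rule named up to 2 members per list with the highest promoter signal, up to 2 with the most distal regions, members in the minority where 5 or fewer had or lacked a promoter region, the 10 genes with the most distal regions and the 5 strongest regions. Lists at promoters were compared with all other genes by a two-sided Fisher's exact test. Lists at distal regions were compared with 10000 random lists matched in 20 bins of assignable length, two-sided. Matches of each consensus within 75 bases of the summit were compared with those in flanks starting 200 bases away by an exact binomial test, and a call also needed a ratio beyond all of up to 20 permuted versions. The p-values for lists and motifs were adjusted by Benjamini-Hochberg over the lists or motifs of a family, with calls at 0.05. Tests of the Hox groups against each other and of copies or mitochondrial sequence in the strongest regions were not adjusted. Intervals are exact (Clopper-Pearson or conditional binomial) at 95%, and cover counting error only. Genes and regions are not independent replicates, so these tests describe the libraries.

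The steps were tested on simulated data. Of 100 unchanged lists of distal counts 4 were called at an unadjusted level, of 15 lists raised 1.5 times 6 were called, and of 15 raised 3 times 14 were called, all over 21853 genes. Of 3 planted motifs 3 were called, and of 24 motifs that were not planted 1 was called, over 15000 regions. Lists of this size therefore can miss changes of 1.5 times. The simulated counts were Poisson draws in proportion to assignable length. The simulated sequences were independent bases of the same composition throughout, without a gradient from summit to flank. Real data can differ from both, so these rates need not carry over.

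Alternatives were other lists, overlap rules, windows, thresholds, backgrounds and the list of each replicate alone. Strongest and removed regions were searched with BLAST+ 2.17.0 in the reference genome, with a further copy defined as 90% identity over 80% of the length. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.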

Results

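Open chromatin was measured by ATAC-seq in the neural tube of mouse embryos at embryonic day 13.5. In this assay a transposase cuts and tags accessible DNA, so that regions rich in cuts mark open promoters and other regulatory DNA. The tissue came from embryos of both sexes of the strain B6NCrl. The 2 libraries were biological replicates of 1 group, so no comparison between conditions was possible. The comparisons here are between the replicates, between parts of the genome and between groups of genes within this tissue. The tissue list, made by the authors from both replicates, held 25300 open regions with 76471 summits, covering 27.0 Mb of the mouse genome (build mm10). The median region was 1070 bases wide and had a signal of 6.62, the authors' enrichment over background. Read totals were not given in the sources used here. The background read level recovered from the deposited values was 4.59 in replicate 1 and 3.48 in replicate 2, so replicate 1 was 1.32 times as deep by this measure.

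The replicates opened largely overlapping parts of the genome. Replicate 1 had 21322 regions and replicate 2 had 16274. Of these, 15093 regions of replicate 1 (70.8%) and 15238 of replicate 2 (93.6%) overlapped a region of the other replicate, or 80.7% of all regions of both lists. Positions shifted along the chromosomes overlapped in 1.47% on average and in at most 1.70% over 100 shifts. Across the 15093 shared pairs, the signal of the replicates correlated with a Spearman rho of 0.901 and a Pearson r of 0.894 on the log2 scale. These are correlations across regions, which are not independent replicates. The regions found only in replicate 1 were weaker, with a median signal of 5.52 against 8.35 for its shared regions. In replicate 2 these medians were 5.61 and 7.97. The lists were called separately, so a region in 1 list only was not shown to differ between the replicates.

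Promoters made up the largest class of regions in the tissue list. There, 12243 of 25300 regions (48.4%, exact Clopper-Pearson 95% interval 47.8 to 49.0) had their strongest summit within 1 kb of a start site of a protein-coding gene, where 2.44% of the assembled genome lies, a 19.8-fold excess. Regions between genes made up 28.2%, introns 21.3% and exons 2.09%, which were 0.469, 0.607 and 0.900 times their shares of the genome. Promoter regions were also the strongest and widest class, with a median signal of 8.64 and a median width of 1291 bases, against 5.87 and 848.5 bases between genes and 5.35 and 794 bases in introns. The promoter share was 54.7% in replicate 1 and 65.2% in replicate 2, which gives an SD of 7.43 percentage points (n = 2). It moved with the depth of the list, from 23.4% in the longer replicated list of 67103 regions to 68.4% in the stronger 50% of regions. Of 21853 protein-coding genes, 12658 (57.9%) had a region within 1 kb of a start site, with 55.6% in replicate 1 and 51.4% in replicate 2.

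Genes of neural progenitors, of neurons in general and of dividing cells had open promoters more often than other genes. All 15 of 15 progenitor genes had a promoter region, against 57.9% of other genes (adjusted p = 0.0013, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 20 lists). Among them were Id4, a helix-loop-helix regulator (signal 9.66 ± 0.97, SD, n = 2), Fabp7, a lipid carrier of radial glia (7.62 ± 0.45), and Sox2, a transcription factor of neural stem cells (6.07 ± 0.97). All 15 pan-neuronal genes also had one (exact adjusted p = 0.0013), including Syt1, a calcium sensor of synaptic vesicles (13.9 ± 0.059, SD, n = 2), and Nrxn1, a synaptic adhesion molecule (13.2 ± 1.0). For replication and mitosis genes it was 15 of 16 (adjusted p = 0.0073, exact test), led by Mcm3 of the replicative helicase (16.6 ± 0.47, SD, n = 2) and Pcna, the polymerase clamp (15.4 ± 0.69). Ccnd1 was the 1 member without a promoter region. Housekeeping genes had one in 16 of 16 (exact adjusted p = 0.0012), for example Sdha at 12.8 ± 0.71, which has a start site of Ccdc127 within 2 kb. Without replicate 1, the progenitor list fell to 11 of 15 and was not called (adjusted p = 0.15, exact test). In the stronger 50% of regions it had 3 of 15 (20%), below the 43.8% of other genes, and the pan-neuronal (8 of 15) and housekeeping (11 of 16) lists were not called (exact adjusted p = 0.60 and 0.082). Against random lists matched on promoter CpG content, the cell cycle list was not called (91.7% in those lists, permutation adjusted p = 1).

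Regulators that differ along the tube were open in part of their members. Of 25 dorsoventral domain genes, 12 had a promoter region (48.0%, exact adjusted p = 0.40), with the highest tissue-list signals at Nkx6-1 of the ventral progenitors (7.20) and Msx2 of the roof plate region (6.92). Of 28 transcription factors of spinal neuron classes, 15 had one (53.6%, exact adjusted p = 0.74), led by Sim1 (9.96) and Foxp1 (8.45). The counts were 13 of 20 for patterning signals, including the Shh transducer Smo (10.5), 8 of 15 for glial genes, including Nfia (8.10), and 10 of 15 for neural crest and sensory genes, none of which was called (exact adjusted p = 0.72, 0.80 and 0.71). The crest list stood below other genes without replicate 1 (7 of 15), as did patterning signals without replicate 2 (11 of 20), both uncalled. Mpz, the highest of the crest list at 11.5, has a start site of Sdhc within 2 kb, and Nfia one of E130114P18Rik. Against random lists matched on CpG content, the dorsoventral list was lower (84.1% in those lists, permutation adjusted p = 0.0008) and so was the spinal neuron list (76.2%, adjusted p = 0.0073). In the longer replicated list both were higher than other genes, at 88.0% and 85.7%, but no comparison matched on CpG content was made there. Without replicate 1 the dorsoventral list was called lower than other genes (3 of 25, exact adjusted p = 0.00031). The dorsoventral and spinal neuron lists were called lower in the stronger 50% of regions (2 of 25 and 6 of 28, exact adjusted p = 0.00076 and 0.032), as was the crest list (2 of 15, 0.030).

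Hox genes, which encode position along the body axis, were open unevenly across the clusters. Of the 27 genes of paralog groups 1 to 9, 20 had a promoter region (74.1%, exact adjusted p = 0.17), with the highest signals at Hoxc4 (7.04) and Hoxa1 (6.85). Of the 12 genes of groups 10 to 13, which act in the caudal body and the limbs, only Hoxc10 (6.91) and Hoxd10 (4.87) had one (16.7%), fewer than other genes (adjusted p = 0.011, exact test). The difference between these 2 groups of Hox genes, tested after the values were seen, had a two-sided Fisher's exact p of 0.0014. Without replicate 1, groups 1 to 9 had 9 of 27, below the 51.4% of other genes (exact adjusted p = 0.11), against 2 of 12 for groups 10 to 13, a difference that was not resolved (exact p = 0.45). In the stronger 50% of regions the counts were 2 of 27 and 1 of 12 (exact p = 1), and groups 1 to 9 were called lower than other genes there (7.41% against 43.9%, exact adjusted p = 0.00049). By cluster, 6 of 11 Hoxa, 7 of 10 Hoxb, 3 of 9 Hoxc and 6 of 9 Hoxd genes had a promoter region. Forebrain and midbrain regulators had one in 6 of 21 (28.6%, exact adjusted p = 0.013), with Arx highest (6.71), a call that was lost without genes that have a neighbouring start site (6 of 20, exact adjusted p = 0.073). The call for Hox groups 10 to 13 was lost in the IDR-thresholded list (33.3%, exact adjusted p = 0.20), and both lists stood above other genes, uncalled, in the replicated list (66.7% and 76.2% against 64.9%). Hox genes lie side by side in clusters, so their counts are not taken as independent.

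Marker genes of other cell types that a dissected neural tube could hold were mostly without promoter regions. No macrophage gene of 14 had one (adjusted p = 5.4e-05, exact test), and the counts were 2 of 14 for skeletal muscle, 2 of 15 for erythroid cells, 2 of 16 for hepatocytes and 2 of 14 for keratinocytes (adjusted p = 0.0034, 0.0022, 0.0013 and 0.0034). Those with a region were Actn2 (14.6) and Mylpf (9.48) for muscle, Klf1 (5.48) and Tfrc (11.1) for erythroid cells, Apoa1 (10.6) and Trf (5.004) for liver, and Lor (7.52) and Perp (7.58) for surface epithelium. Tfrc, a receptor for iron uptake in dividing cells of many kinds, is not restricted to blood. Mylpf and Trf have a start site of another gene within 2 kb. Endothelial genes had a promoter region in 6 of 15 and mesenchyme and somite genes in 6 of 17, neither called (exact adjusted p = 0.26 and 0.13). Both were called lower in the stronger 50% (exact adjusted p = 0.0067 and 0.00049) and within 500 bases of a start site (0.032 and 0.040). The mesenchyme count was 0 of 17 in replicate 1 and 4 of 17 in replicate 2, and both replicate lists were called lower (adjusted p = 1.0e-05 and 0.039, exact test). Endothelial genes had 3 of 15 in each replicate and were also called lower there (exact adjusted p = 0.012 and 0.030). Only 2 of 1133 olfactory receptor genes, Olfr94 and Olfr958, had a promoter region (0.177%, against 61.1% of other genes). Against lists matched on promoter CpG content, the muscle, erythroid, macrophage, hepatocyte and keratinocyte lists were not called (permutation adjusted p = 0.054, 0.31, 0.25, 0.70 and 0.31), while olfactory receptors, Hox groups 10 to 13 and forebrain genes stayed lower (adjusted p = 0.0008 for each). In the replicated list, muscle (5 of 14) and erythroid genes (6 of 15) were not called (exact adjusted p = 0.069 and 0.081).

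**Figure D1:**
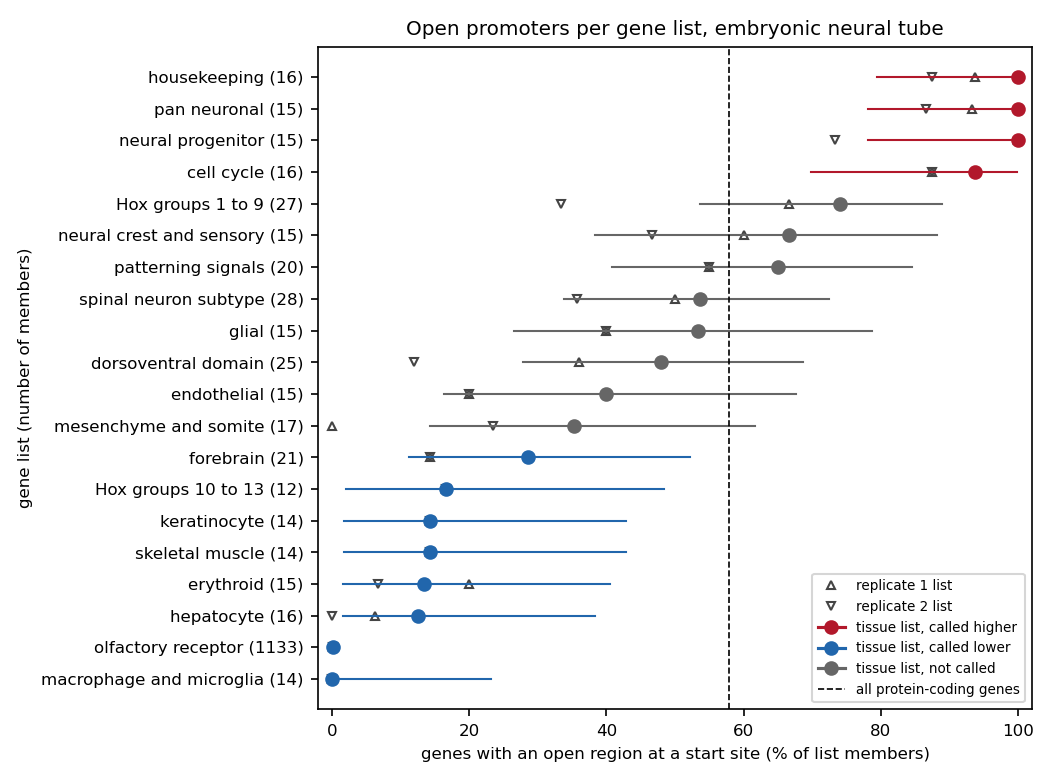
Share of the members of each gene list with an open region within 1 kb of a start site (x axis, percent), for the tissue list (filled points with exact 95% intervals) and for the list of each replicate (triangles). Progenitor, pan-neuronal and housekeeping genes reach 100%, against the 57.9% of all protein-coding genes (dashed line), and macrophage genes lie at 0.

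Distal open regions, more than 1 kb from every start site of a protein-coding gene, gathered around genes of neural development. There were 12714 such regions assigned to the nearest gene up to 500 kb away, on average 0.582 per gene. The list of replicate 1 gave 9408 and that of replicate 2 gave 5523. Progenitor genes had 3.53 each. The geometric mean of 1 + count was 2.22 times that of random lists with the same length of surrounding sequence (permutation adjusted p = 0.0008; folds here are this ratio, not a ratio of counts), with 11 at Sox2 and 6 at Id4. Dorsoventral genes had 2.64 (1.93-fold, permutation adjusted p = 0.0008), with 10 at Pax3, a dorsal progenitor regulator, and 5 at the proneural gene Ascl1. Glial genes had 3.47 (1.92-fold, permutation adjusted p = 0.0008), with 13 at Nfib and 12 at Sox9, transcription factors of the switch to glia. Patterning signals had 2.70 (1.69-fold, permutation adjusted p = 0.0013), with 7 at the retinoic acid receptor gene Rarb and 7 at Gli2 of the Shh pathway. Pan-neuronal genes had 3.33 (1.62-fold, permutation adjusted p = 0.0086), with 11 at Nrxn1 and 9 at Ncam1, and spinal neuron factors had 1.82 (1.34-fold, adjusted p = 0.031), with 5 at Sim1 and 5 at Lmx1b. Hox groups 1 to 9 had 0.667 (1.33-fold, permutation adjusted p = 0.0008; 0.525 against 0.108 in mean log2 of 1 + count), with 5 at Hoxd3, whereas Hox groups 10 to 13 had 0 (adjusted p = 0.61).

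Forebrain genes had 0.667 distal regions each (0.906-fold, permutation adjusted p = 0.61), and neural crest and sensory genes had 1.53 (1.22-fold, adjusted p = 0.38). None of the lists of mesenchyme, muscle, endothelial, erythroid, macrophage, hepatocyte, keratinocyte, cell cycle or housekeeping genes was called, with 0.892-fold to 1.17-fold values and permutation adjusted p from 0.24 to 0.93. Mesenchyme (0.953-fold) and muscle genes (0.969-fold) without replicate 1, mesenchyme without replicate 2 (0.880-fold) and hepatocyte genes without either (1.02-fold and 1.09-fold) lay on the other side of 1, uncalled. In the replicated list forebrain (5.14 per gene), crest (7.93) and muscle genes (2.64) were called higher (permutation adjusted p = 0.030, 0.0040 and 0.016), as was the crest list without matching on length (0.0045). Single members of these lists could still have many, such as Ptprc, a leukocyte surface gene, with 8, and the proliferation marker Mki67 with 7. Olfactory receptor genes had 0.0335 each, fewer than random lists (0.909-fold, permutation adjusted p = 0.0008). The p-values come from 10000 random lists, whose smallest unadjusted p is 0.0002, and describe these libraries, since genes are not independent replicates. Without replicate 1, the dorsoventral (0.88 per gene, permutation adjusted p = 0.076), glial (1.20, 0.072), pan-neuronal (1.33, 0.054) and spinal neuron (0.857, 0.073) lists were not called. Without replicate 2, the spinal neuron list was not called (1.18, permutation adjusted p = 0.12), nor was it in the IDR-thresholded list (0.11). In the stronger 50% of regions, 3 lists were called in place of 8, and Hox groups 1 to 9 had no distal region there. The Hox groups 1 to 9 call also depended on matching for length (permutation adjusted p = 0.62 unmatched).

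**Figure D2:**
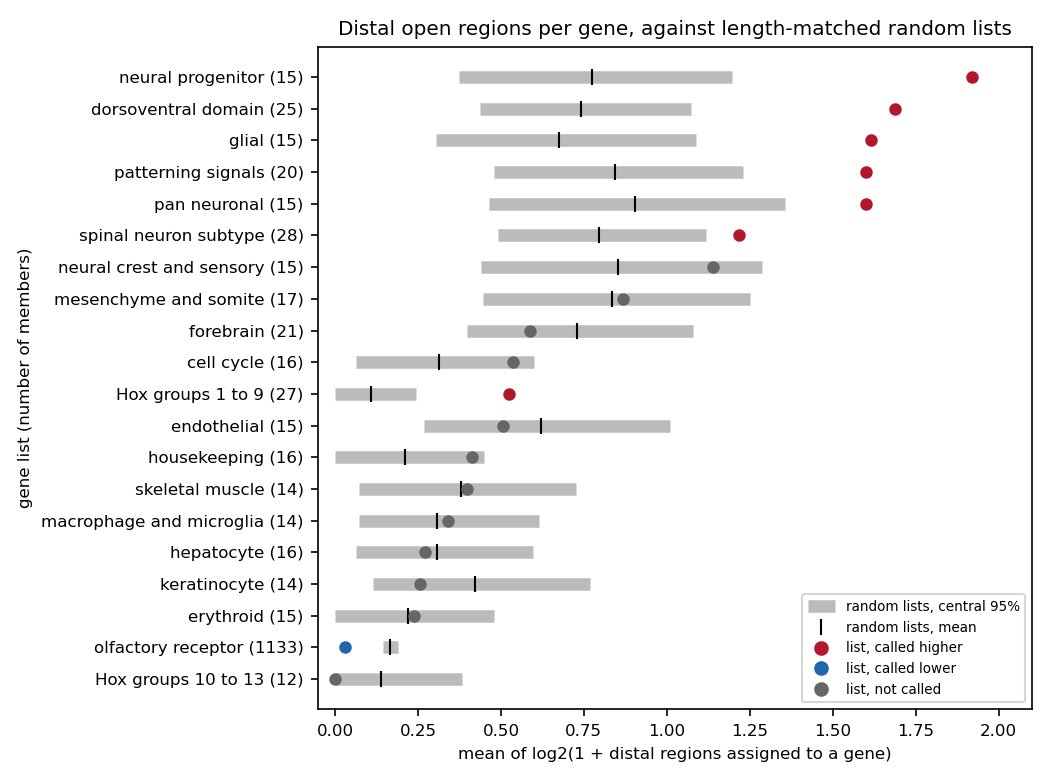
Mean of log2(1 + distal open regions assigned to a gene) for each gene list (points), with the mean and central 95% of 10000 random lists of equal size matched on the length of surrounding sequence (ticks and grey bars). Progenitor genes lie farthest to the right at 1.92, against a mean of 0.773 for their random lists.

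Of single genes, Auts2, a regulator linked to neurodevelopment, had the most distal regions in the tissue list, 20 (17 in replicate 1 and 12 in replicate 2). Myt1l, a neuronal transcription factor, had 19. They were followed by Ubash3b and Zmiz1 with 18, Gm11146 with 17, and Tmem161b, the synaptic adhesion gene Nrxn3, the corepressor gene Tle3, the neuronal RNA-binding protein gene Celf4 and Gse1 with 16 each. The order of these genes changed in each replicate alone. In replicate 1, Gm11146 and Tmem161b had the most among them, 18 each, and Celf4 had the fewest, 8. In replicate 2, Tmem161b had the most among them, 14, and Nrxn3, Celf4 and Gse1 had the fewest, 6 each. Ubash3b had 17 in replicate 1 and 9 in replicate 2, and Zmiz1 had 11 and 7. The counts were not corrected for the surrounding length, which was 1643.5 kb for Auts2 and 353 kb for Gse1. The nearest gene need not be the one that a region regulates.

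The 5 regions of highest signal lay between genes and were narrow. The strongest, on chromosome X from 143482936 to 143483180, had a signal of 53.8 in the tissue list, 48.4 in replicate 1 and 52.3 in replicate 2, and lay 35531 bases from the nearest start site, that of Pak3. The next were on chromosome 2 from 69355470 to 69355735 (42.1, nearest gene Abcb11), chromosome 2 from 3964425 to 3964690 (41.6, Frmd4a), chromosome 5 from 60042766 to 60043138 (34.5, G6pd2) and chromosome 10 from 96077549 to 96077951 (31.8, Gm5426). Those on chromosomes 5 and 10 matched the mitochondrial genome over 89.5% and 86.6% of their length, at 97.6% and 97.4% identity, and the one near Abcb11 over 48.5%.

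Sequence around the summits of the 13057 distal regions was enriched for binding sites of known regulators. Within 75 bases of the summit, the consensus of CTCF, which organises chromatin loops, occurred 907 times against 70 in flanks of the same total length, a ratio of 12.96 (exact 95% interval 10.2 to 16.8). RFX sites, bound by regulators of ciliary genes, had a ratio of 8.27 (6.19 to 11.3), SP/KLF sites 5.46, NFY sites 3.26 and ETS sites 2.79. Among regulators of neural and axial identity, the PBX-HOX site had a ratio of 2.74 (1.59 to 4.90), the proneural E-box 2.18 (2.05 to 2.32), the POU octamer 1.86 (1.60 to 2.17), SOX 1.29 (1.14 to 1.46) and the homeodomain site TAATTA 1.16 (1.05 to 1.29). The AP-1 site had 1.32 (1.13 to 1.54). These 11 of 27 consensus sequences were called because the adjusted p was under 0.05 and the ratio exceeded every permuted version of the sequence. Sites of blood and liver regulators were not called, with 0.568 for GATA, 0.826 for SPI1 and 0.750 for HNF4, and HNF1 had no match. The spinal neuron list also holds Gata2 and Gata3, so the GATA site does not stand for blood alone. HNF4 was called lower in the replicated list (0.673, exact adjusted p = 0.022) and with flanks from 400 bases (0.385, adjusted p = 0.0029). NRF1 (11, 22 against 2 matches), NFI (4.67, 14 against 3) and ZIC (2.02) did not exceed all of their permuted versions, nor did GLI (0.810), TCF/LEF (0.806) or MEIS (0.992).

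Promoter summits had a different order of sites, with NFY at 12.1 (10.3 to 14.2), ETS at 8.07, NRF1 at 5.45, SP/KLF at 4.90, RFX at 4.52, CTCF at 3.08 and the POU octamer at 2.33. The EBF site was called lower there (0.571), and the SOX (0.803), TAATTA (0.330), AP-1 (0.948), E-box (1.11) and PBX-HOX (2.33) sites were not called. The difference between distal and promoter summits was not itself tested. In distal regions, TAATTA was also not called in the IDR-thresholded list (1.056), the replicated list (1.04) or the stronger 50% (1.03), nor AP-1 in the stronger 50% (1.21), nor ETS in the replicated list (1.62). With flanks from 400 bases AP-1 (1.12) and ETS (2.79) were not called, nor was SP/KLF with a centre of 50 bases (5.81). Without replicate 1, SOX (1.18), AP-1 (1.22), SP/KLF (4.47), PBX-HOX (3.33) and TAATTA (0.967) were not called in distal regions, and TAATTA was not called without replicate 2 either (1.062). Uncalled sites also crossed 1, with TEAD at 0.866, TCF/LEF at 1.13 and MEIS at 1.07 without replicate 1 and MEIS at 1.16 without replicate 2. NRF1 was called in the list of each replicate alone (10.0 in replicate 1 and 17.0 in replicate 2) and in the stronger 50% (11), and NFI in the replicated list (5.09, 56 against 11 matches) and with a centre of 50 bases (12).

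**Figure D3:**
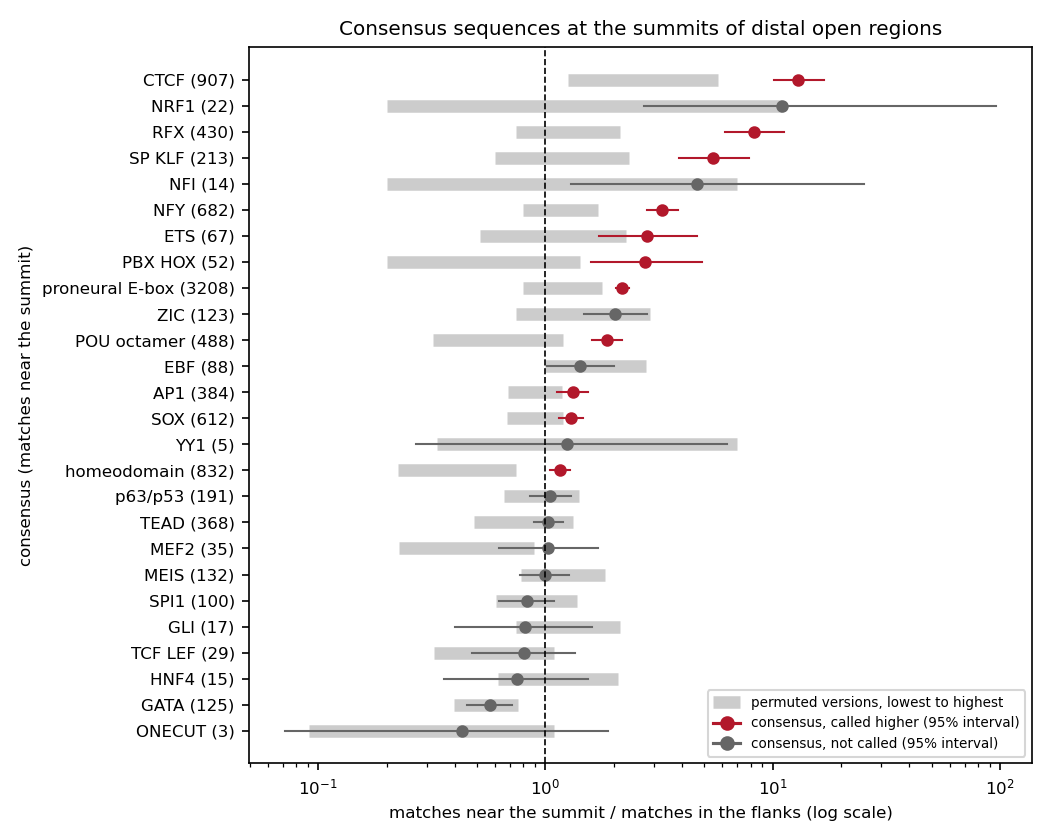
Ratio of consensus matches within 75 bases of the summits of distal open regions to matches in the flanks (x axis, log scale), with exact 95% intervals and the range of permuted versions (grey bars). CTCF lies highest at 12.96, and 11 of the 27 sequences are called, all above 1.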

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

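The test of depth, the Fisher's exact tests and the count without the mitochondrial genome were chosen after the values were seen, and the other tests in this part before. Apart from CTCF sites at the strongest distal regions, no biological explanation was tested, since the design has 1 group.

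The ranked list of the series holds a signal that the thresholded lists leave out. Its region of lowest p, on chromosome 1 from 24611587 to 24616168, had a −log10 p of 6117.94 with a signal of only 3.58. All of it (100%) matched the mitochondrial genome at 95% identity or more, with 99.956% over the longest match. Mitochondrial reads placed on a nuclear copy are a candidate source. The ranked list also had 76 summits at an IDR of 0.05 on sequences outside the 21 chromosomes, which the tissue list leaves out. Of the 57 removed regions on the chromosomes, 23 had a further copy in the assembly.

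A related pattern remained in the tissue list, where the 20 strongest regions outside promoters were narrow (median 469 bases, against 799.5 for 200 random distal regions). For CTCF sites, 0 of the 20 held the consensus near the summit, which met the bound set beforehand against them. The consensus was rare in random distal regions too (7 of 200). The count therefore cannot argue against CTCF sites, and a lack of matches does not show that CTCF is unbound. A further copy in the assembly was found for 11 of the 20, against 3 of 200 random distal regions (Fisher's exact p = 4.8e-11), which is over the bound of 10 set beforehand. That count is 10 if the mitochondrial genome is not taken as a copy. The regions on chromosome 8, at ranks 8, 16, 17 and 20 of the 20, had 6 further copies each and may be copies of 1 sequence. Counted once, they would bring the count under the bound. The Fisher's exact test takes regions as independent, which these may not be. Mitochondrial sequence covered at least 50% of 5 of the 20, against 1 of 200 (Fisher's exact p = 2.1e-05), between the bounds set beforehand. These 5 were narrow, at 343 to 491 bases. Regions with a further copy but no mitochondrial match were 745 to 1038 bases wide, so repeated nuclear DNA did not go with narrow width. Reads from repeated or mitochondrial DNA may account for part of the high signal. For 8 of the 20, the strongest on chromosome X among them, neither was found at these bounds, and their signal stays open. The region near Abcb11, also among these 8, fell just under the bound, with a mitochondrial match over 48.5% of its length at 100% identity.

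Replicate 1 gave more regions than replicate 2, and a smaller share of them lay at promoters (54.7% against 65.2%). Replicate 1 was 1.32 times as deep by its background level. Of the regions found only in replicate 1, 90.3% were in the ranked list of replicate 2, but so were 96.1% in the other direction, so these shares do not decide whether depth gave the longer list. When replicate 1 was limited to its 16274 strongest regions, the gap in promoter share shrank from 10.5 to 4.32 percentage points. This lies between the bounds set for list length as the cause, so that test did not decide for the whole gap. The remaining 4.32 points stand between lists of equal length, but replicate 1 was cut further by signal and replicate 2 by IDR alone. This comparison therefore does not separate list length from the rule of the cut for these points. Their source was not tested, with 1 library each.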

How the results depend on the processing

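The settings without neighbouring start sites and with equally long replicate lists, and those for the 2 groups of Hox genes, were chosen after seeing the data. No paired analysis was possible because there is 1 group. Unless a construction is named, the cause was not tested. The HNF1 site had no match and no value under any setting.

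The share of regions found in both replicates (80.7%) was 76.7% at a reciprocal 50% overlap, 70.5% with summits within 100 bases, 82.4% in the stronger 50% of each list, 81.3% with the top 20000 regions (all of replicate 2) and 72.6% in the pseudoreplicated lists. Rho (0.901) was 0.909 for summits within 100 bases, 0.839 in the pseudoreplicated lists and 0.821 in the stronger 50%. The promoter share (48.4%) was 23.4% in the replicated list, 68.4% in the stronger 50%, and 60.9% in replicate 1 at the length of replicate 2. It ranged from 54.7% to 65.2% when a replicate was left out, and stayed within 1 SD with other windows and the IDR-thresholded list.

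The number of lists called at promoters (12, with 4 higher and 8 lower) was within 1.5 times under all settings, but the directions moved, with 1 higher and 14 lower in the stronger 50% and 8 higher and 4 lower in the replicated list. Against lists matched on CpG content 8 were called, with the muscle, erythroid, macrophage, hepatocyte, keratinocyte and cell cycle lists lost and the dorsoventral and spinal neuron lists gained as lower. Of 180 single values, 130 kept direction and side of the threshold, 13 lost and 15 gained a call, and 22 turned against their background. These were dorsoventral (88.0%), spinal neuron (85.7%), glial (73.3%), Hox groups 10 to 13 (66.7%), forebrain (76.2%) and mesenchyme genes (70.6%) in the replicated list, and progenitor (20%), Hox groups 1 to 9 (7.41%), patterning (35%) and crest genes (13.3%) in the stronger 50%. Spinal neuron and glial genes turned in the IDR-thresholded list (60.7% and 60%) and without neighbouring start sites (53.6% and 53.8%), and patterning and crest genes with the outermost start site (50% and 46.7%). Against lists matched on CpG content, glial (53.3%), patterning (65%) and crest genes (66.7%) turned with the same values. Without a replicate, Hox groups 1 to 9 ranged from 33.3% to 66.7%, crest genes from 46.7% to 60% and patterning at 55% in both. Without genes that have a neighbouring start site 11 lists were called, the forebrain list being lost. The difference between the Hox groups (57.4 points) was −0.926 in the stronger 50%.

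Calls at distal regions (8) were 3 in the stronger 50%, which holds fewer regions, and ranged from 4 to 7 when a replicate was left out. Of 140 single values 100 kept direction and side, 11 lost and 3 gained a call, and 26 turned against random lists (regions per gene follow). These were Hox groups 10 to 13 (0.917), forebrain (5.14), endothelial (3.27), erythroid (0.467) and hepatocyte genes (1.69) in the replicated list, Hox groups 1 to 9 (0), erythroid (0.0667) and hepatocyte genes (0.25) in the stronger 50%, and mesenchyme (1.059) and hepatocyte genes (0.5) in the IDR-thresholded list. Up to 100 kb they were forebrain (0.667), mesenchyme (0.647), muscle (0.357), erythroid (0.133) and macrophage genes (0.214), and without matching on length forebrain (0.667), muscle (0.429), endothelial (0.667), erythroid (0.267), macrophage (0.714) and housekeeping genes (0.5). Without a replicate, mesenchyme ranged from 0.353 to 0.529, muscle from 0.143 to 0.357 and hepatocyte genes from 0.25 to 0.5.

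Called motifs (11) ranged from 7 to 11 when a replicate was left out. Of 208 single values 155 kept direction and side, 15 lost and 8 gained a call, and 30 crossed or reached 1. At promoter regions these were SOX (0.803), TAATTA (0.330), AP-1 (0.948), EBF (0.571), TEAD (0.667), MEIS (1.34), GLI (1.07), ONECUT (1.5), SPI1 (1.33) and P63/P53 (0.96). In the replicated list they were MEF2 (0.955), MEIS (1.09), GLI (1.05), SPI1 (1.03) and P63/P53 (0.985), in the stronger 50% TEAD (0.878), MEF2 (0.636), MEIS (1.07) and P63/P53 (0.985), in the IDR-thresholded list MEIS (1.05) and GLI (1.17), and with flanks from 400 bases MEF2 (0.921), MEIS (1), GLI (1.31) and P63/P53 (1). Without a replicate, TAATTA ranged from 0.967 to 1.062, TEAD from 0.866 to 1.02, MEIS from 1.07 to 1.16 and TCF/LEF from 0.727 to 1.13. Depth is known only as the ratio of 1.32 between the replicates, so how many weak regions deeper libraries would add was not tested.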

Other observations

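The tests of signal by site, of the pseudoreplicated lists and of the Hox groups against each other were chosen after the results on the tissue list were seen, and the replicated list was set beforehand. Weaker open regions, which the tissue list leaves out, added many promoters of regional regulators. In the replicated list of 67103 regions, 26 of 27 genes of Hox groups 1 to 9 had a promoter region (adjusted p = 0.0012, two-sided Fisher's exact test over the 20 lists), as did 22 of 25 dorsoventral genes (0.038), 24 of 28 spinal neuron factors (0.045) and 14 of 15 neural crest and sensory genes (0.045), each more than the 64.9% of other genes. Forebrain genes also rose, from 6 to 16 of 21, and Hox groups 10 to 13 from 2 to 8 of 12, neither called. Markers of macrophages (1 of 14), hepatocytes (4 of 16) and keratinocytes (3 of 14) stayed lower (exact adjusted p = 0.00012, 0.0052 and 0.0040). None of these comparisons was matched on CpG content. Mesenchyme genes had 12 of 17 (exact adjusted p = 0.84). In the pseudoreplicated list of each replicate they had 11 and 9 of 17, against 0 and 4 in the thresholded lists.

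Sites at the summit went with the strength of distal regions for some factors. Those with an NFY site had a median signal of 6.49 against 5.61 without (adjusted p = 4e-05, permutation test with 100000 resamples of mean log2 signal, over 11 sites; the unadjusted p of 1e-05 is the smallest it can give). With ETS it was 7.63 against 5.62 (permutation adjusted p = 4e-05), and with SP/KLF 5.82 against 5.62 (adjusted p = 0.012). All 3 held in each replicate, with adjusted p from 5e-05 to 0.018. RFX had 6.05 against 5.62 (permutation adjusted p = 4e-05) but did not pass in replicate 2 (adjusted p = 0.16). CTCF, the most enriched site, had 5.75 against 5.62 (permutation adjusted p = 0.15). Promoters of genes that do not code for protein can be among these distal regions and were not separated.

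A hypothesis concerns the Hox genes of groups 10 to 13, which lacked promoter regions in the tissue list more often than those of groups 1 to 9, though this was not resolved in replicate 2 alone (2 of 12 against 9 of 27, exact p = 0.45). Their signal may be too weak to pass the threshold, which is set on the IDR, rather than absent. Of the 10 genes without a region in the tissue list, 6 (60%) had one in the replicated list, while Hoxa11, Hoxa13, Hoxc12 and Hoxd12 had none. Of the 7 genes of groups 1 to 9 that lacked one in the tissue list, 6 had one there too (85.7%). The groups still differed in the replicated list (8 of 12 against 26 of 27, exact p = 0.025). Signal alone did not set which genes passed, since Hoxc13 had 4.93 without a tissue-list region and Hoxb2 had 2.66 with one. In the replicated list some of the 10 genes thus had a signal and others none. Weak and absent signal therefore cannot be told apart as the source of the difference between the groups. The highest promoter signal in that list had a median of 3.16 for groups 10 to 13, with absent regions taken as 0, and 3.86 for groups 1 to 9, a difference that was not resolved (permutation p = 0.14). How far along the body axis the tissue was taken was not analysed here and stays an open explanation.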
